A study of Mus musculus with 19 samples.

How the data were processed

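Total RNA of 19 mouse lungs was measured on Affymetrix arrays. Per the labels' protocols, RNA was extracted with QIAzol and RNeasy, had an integrity number above 8.5, and 700 pg of it were turned into cDNA, fragmented and labelled with biotin with the GeneChip Pico kit. The deposited values are log2 expression per probe set, made by the authors with Affymetrix Expression Console and RMA (background correction, normalization across arrays and summary of probes), per the submitters' processing notes, whose versions are not given in the sources used here. The table held 22206 probe sets on 19 arrays with 2 decimals, values from 2.07 to 19.93, 0 missing values and 0 columns that could not be matched to a sample by name. No further normalization was applied.

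Probe sets were named from the platform annotation. Of the 22206, 19572 had 1 gene symbol, 0 had several and 2634 were unnamed here, and all 19572 symbols were found by their gene number with 0 changed. Counts of calls run over all probe sets, and lists and named genes use 1 probe set per gene (19505 genes), the one with the highest mean over all arrays. Arrays have no read depth. As a measure of background, 1449 probe sets of odorant, vomeronasal and taste receptor genes, which lung is not known to use, had a median of 3.51 and a 95th percentile of 4.75, and 35.5% of probe sets had a mean below that value, where a difference is hard to see. At the other end, 6 probe sets stood at the top of the scale on all arrays. The smallest SD of the difference between 2 arrays was 0.411, so each array holds values of its own.

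Samples were grouped by the group label and named by group and replicate number: CS-PBS (n = 4), CS-hBD2 (n = 5), RA-PBS (n = 5; the series design text calls its treatment vehicle) and RA-hBD2 (n = 5). The treatment protocol is the same text on all samples, so smoke and hBD2 were assigned from the group label. A model with 4 group means was fitted to all 19 arrays with limma (lmFit and eBayes), so that the groups share 1 spread per probe set (residual degrees of freedom 15, prior 6.41, median residual SD 0.31). Comparisons were smoke in vehicle-treated and in hBD2-treated lungs, hBD2 in smoke and in room air, the interaction and the hBD2 effect averaged over both exposures. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all 22206.

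Lists of 19 pathways and 22 cell types, 41 in all, were fixed before the data were examined. Of these 40 had at least 5 measured genes and were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 40; the sex-linked list was given as values. As fixed lists they share some members, such as Ctsk, Lcn2 and Mmp12. Each test was run again with the correlation between a list's genes estimated from the residuals, and with fry, which asks whether a list's genes move one way on balance without comparing them with other genes. Counts of members are given over all probe sets and adjusted over the list alone. A list score per array is the mean over its genes of the log2 value minus the gene's mean over all arrays, and was compared between groups by an exact two-sided permutation test over all 126 splits, adjusted over 40 lists. Correlations of effects across probe sets have a jackknife SE over arrays and a value from 100 simulations with no effect.

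The genes named follow a rule fixed with the design. It takes the 10 largest changes each way among called genes (leaving out Gm, Rik, LOC, clone and Mir names), or, where none pass, the 5 with the smallest p; up to 4 members with the smallest p of each list discussed; and a set of single genes whatever their values, chosen for smoke, defensin receptors, inflammation, mucus and sex, of which Xist and Ddx3y had no probe set here. Genes given for comparisons without 1 array were chosen after their values were seen.

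The alternatives were eBayes with trend and robust estimates, quantile normalization, a shift to a common median, filters at the 25th percentile (3.92) and the median (6.74) of mean signal, array weights, fits on only the groups compared, the replicate number as a block, only probe sets with 1 symbol, a fold floor of 1.5, an adjusted p under 0.1, lists with an estimated correlation or fry, and leaving out each array. Shared controls were handled by simulation, covariance and splits of the shared arrays. Tests were checked on simulated data for all 22206 probe sets with 200 changed ones. Of those changed 1.5-, 2- and 4-fold, the fit recovered 2.99%, 64.2% and 100% for smoke in vehicle-treated lungs (1 false call of 112), 14.9%, 67.2% and 100% for hBD2 in smoke (3 of 124), 23.9%, 67.2% and 98.5% for hBD2 in room air (4 of 130) and 26.9%, 82.1% and 100% for smoke in hBD2-treated lungs (11 of 150). Each comparison was simulated in 1 draw, with noise independent between probe sets. Differences between these percentages thus include those of the draw, and false calls among correlated genes were not measured. The work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.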

Results

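Transcript levels were measured in mouse lung on 19 Affymetrix arrays, 1 per lung sample. The design crossed cigarette smoke with human beta-defensin 2 (hBD2), a small antimicrobial peptide made by epithelial cells. Mice breathed room air (RA) or were exposed to cigarette smoke (CS) for 7 weeks at 2 h per day. They received hBD2 or its vehicle into the nose in the last 2 weeks and were sacrificed at 5 months of age. There were 4 CS-PBS arrays (smoke and vehicle), 5 CS-hBD2 arrays, 5 RA-PBS arrays (room air and vehicle) and 5 RA-hBD2 arrays. The labels name each array as a separate sample of its group and say no more about litters, cages, batches or pairing, so each p-value measures the spread between these samples. The values are log2 intensities of 22206 probe sets, with array medians between 6.68 and 6.78 and correlations between arrays of 0.979 to 0.994. The number of arrays limits the precision. The secretory genes Scgb1a1 (club cells) and Sftpc (alveolar type 2 cells) stood at 19.93, the top of the scale, in every group, so a change in them could not be seen. Differences are given on the log2 scale with their standard error (SE) from limma, and adjusted p-values are limma's after Benjamini-Hochberg adjustment unless another test is named. Group means below 4.75, the 95th percentile of receptor probe sets that lung is not known to use, are called within the background.

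The first comparison asked what smoke did to the lung without the peptide (CS-PBS, n = 4, against RA-PBS, n = 5). Genes of lipid-laden and alveolar macrophages were among those that rose. Ear6, a ribonuclease of the eosinophil-associated family, rose by 5.95 ± 0.39 (61.8-fold, adjusted p = 1.34e-09), and the transmembrane glycoprotein gene Gpnmb by 4.79 ± 0.28 (27.6-fold, adjusted p = 6.45e-10). The lysosomal protease gene Ctsk rose by 4.34 ± 0.21 (20.3-fold, adjusted p = 3.77e-11) and Mmp12, the macrophage elastase, by 4.28 ± 0.44 (19.4-fold, adjusted p = 1.41e-06). The chemokine receptor gene Cxcr1 rose by 5.85 ± 0.39, the surface antigen gene Ly6i by 5.23 ± 0.35, the acute-phase gene Saa3 by 4.45 ± 0.71 and the antiprotease-like gene Wfdc17 by 4.40 ± 0.27. The clock output gene Dbp rose by 3.93 ± 0.40 and Ch25h, an enzyme that makes an oxysterol, by 3.88 ± 0.24. All 6 had adjusted p-values of 0.000345 or less. Probes for members of near-identical families such as Ear6 and Ly6i may share signal with their relatives. Among the genes that fell, Zbtb16, a transcription factor induced by glucocorticoids, fell by 4.00 ± 0.30 on the log2 scale (16.0-fold lower, adjusted p = 8.7e-09). The clock activators Arntl and Npas2 fell by 2.57 ± 0.23 and by 2.40 ± 0.38. The platelet genes Ppbp, Gp9 and Tubb1 fell too, with differences of -2.99 ± 0.66, -2.08 ± 0.43 and -1.97 ± 0.32 (adjusted p of 0.00743, 0.00407 and 0.000467). Ccnjl, Fam124b and Cpne5 also fell, with differences of -2.15 ± 0.28, -1.96 ± 0.28 and -1.92 ± 0.26. Cpne5 was at 4.28 in CS-PBS, within the background, so the size of its fall is uncertain. The platelet-expressed gene Nrgn passed at -2.06 ± 0.53 (adjusted p = 0.0234). It lost its call without array CS-PBS 1 (adjusted p = 0.0581), CS-PBS 2 (0.0722), CS-PBS 4 (0.0518) or RA-PBS 5 (0.0679).

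In the same comparison, macrophage and inflammatory gene lists rose together. Of the 20 measured genes of lysosomes and lipid-handling macrophages, 15 rose and 0 fell at the threshold over all probe sets (17 and 1 adjusted over the list alone). The list test camera gave an adjusted p of 1.43e-34, and the adjusted p was 3.9e-05 with an estimated correlation. The proton pump subunit gene Atp6v0d2 rose by 2.95 ± 0.19 and the acid phosphatase gene Acp5 by 2.36 ± 0.18. Of 16 alveolar macrophage markers, 11 rose and 1 fell (12 and 2 adjusted over the list alone; camera adjusted p = 3.07e-21, and adjusted p = 0.000526 with an estimated correlation). Among them were the scavenger receptor gene Marco at 3.85 ± 0.27 and Plet1 at 1.98 ± 0.14. Among 27 chemokine genes 10 rose (14 higher and 1 lower adjusted over the list alone; adjusted p = 0.0269 with an estimated correlation). They included Ccl3 at 3.26 ± 0.42, Ccl6 at 2.94 ± 0.19, Ccl9 at 2.63 ± 0.39 and the neutrophil attractants Cxcl5 at 2.94 ± 0.41 and Cxcl1 at 2.17 ± 0.35. In RA-PBS Cxcl5 (4.21), Cxcl1 (4.07), Csf2 (4.57) and Il1r2 (4.74) were within the background, so the sizes of their differences are uncertain. Of 24 genes of NF-kB and acute inflammation 9 rose (14 adjusted over the list alone; adjusted p = 0.00144 with an estimated correlation). Lcn2, an iron-binding defence protein, was at 1.83 ± 0.19, the growth factor gene Csf2 at 1.56 ± 0.22 and Il1a at 1.48 ± 0.22. Complement (7 of 12 rose; 8 adjusted over the list alone), monocyte and interstitial macrophage markers (7 of 16; 9 higher and 1 lower), and neutrophil markers (8 of 16; 10 higher and 1 lower) also rose, with adjusted p-values of 0.0282, 0.0269 and 0.0282 with an estimated correlation. So did proteases and antiproteases (7 of 22; 9 higher and 1 lower adjusted over the list alone), antimicrobial and secreted defence proteins (8 of 24; 10 higher and 1 lower) and iron handling (6 of 14; 7 higher and 1 lower), with adjusted p-values of 0.00183, 0.0309 and 0.00608 with an estimated correlation. Examples were the complement genes C1qa at 1.92 ± 0.31, C3ar1 at 2.31 ± 0.40 and Cfb at 2.11 ± 0.38 and the endotoxin co-receptor gene Cd14 at 1.31 ± 0.17. Others were the neutrophil granule gene Ltf at 1.84 ± 0.39, the antibody transporter gene Pigr at 2.31 ± 0.31 and Wfdc21 at 2.33 ± 0.29. The neutrophil marker Il1r2, at 1.09 ± 0.27, lost its call without array CS-PBS 1 (adjusted p = 0.0619), RA-PBS 4 (0.0571) or RA-PBS 5 (0.057). Il1b passed at 1.22 ± 0.28 and lost its call without CS-PBS 2 (1.00, adjusted p = 0.0557) or CS-PBS 4 (1.01, 0.0659). Tnf, at 1.80 ± 0.47, lost its own without CS-PBS 4 (1.17, 0.115), RA-PBS 3 (1.59, 0.067) or RA-PBS 4 (1.65, 0.0638).

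Cell division, clock and vessel genes moved as well. Of 22 cell cycle genes 16 rose and 0 fell (20 adjusted over the list alone; camera adjusted p = 3.07e-21, and adjusted p = 0.0269 with an estimated correlation). Among them were the nucleotide-synthesis gene Rrm2 at 2.17 ± 0.31, the replication helicase gene Mcm5 at 1.56 ± 0.26, the mitotic kinase gene Plk1 at 1.67 ± 0.28 and the proliferation marker Mki67 at 2.05 ± 0.34. The 17 circadian clock genes split, with 8 that rose and 4 that fell (11 and 4 adjusted over the list alone; adjusted p = 0.028 with an estimated correlation). The clock repressors Bhlhe41 and Per3 rose by 2.32 ± 0.22 and 2.11 ± 0.27, in the direction of Dbp and against Arntl and Npas2. Endothelial markers fell in 8 of 14 genes, and 13 were lower adjusted over the list alone (adjusted p = 0.0282 with an estimated correlation). Sox18, a vessel transcription factor, had a difference of -1.08 ± 0.23, the endothelin receptor gene Ednrb of -0.81 ± 0.17 and the lipase anchor gene Gpihbp1 of -0.66 ± 0.16. The junction gene Cdh5, at -0.61 ± 0.15, lost its call without array CS-PBS 4 (-0.48, adjusted p = 0.0715). Array CS-PBS 4 had the highest score of its group for cell cycle (1.45, against -0.02 to 0.33 on the other CS-PBS arrays), NF-kB (0.94, against 0.26 to 0.31), chemokines (1.57, against 0.17 to 0.53) and complement (1.48, against 0.10 to 0.47). Without it these 4 lists and the endothelial list still passed with an estimated correlation (adjusted p of 0.00792, 0.000557, 0.01, 0.00792 and 0.0351). The genes called without it were fewer: 9 of 22 for cell cycle, 5 of 24 for NF-kB, 3 of 14 endothelial and 4 of 16 neutrophil markers.

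Other lists passed camera with its preset correlation of 0.01 and not with an estimated one. Interferon gamma and antigen presentation was one of them: 8 of 17 genes passed (16 adjusted over the list alone), and the list had an adjusted p of 0.0538 with an estimated correlation. Among the 8 were the class II regulator gene Ciita at 1.31 ± 0.22, the class II gene H2-Ab1 at 1.01 ± 0.19 and the immunoproteasome gene Psmb9 at 1.28 ± 0.27. The class II gene H2-Eb1, at 0.91 ± 0.21, lost its call without array CS-PBS 4 (0.70, adjusted p = 0.0562). On array CS-PBS 3 the score of this list was -0.36, against 0.75, 1.29 and 0.88 on the other CS-PBS arrays. Without that array, picked once its values were seen, all 17 genes passed and the list's adjusted p was 0.00606 with an estimated correlation. Without array CS-PBS 4, in contrast, 3 of the 17 passed and that adjusted p was 0.075. Immediate early genes (3 of 17 higher, 5 adjusted over the list alone) had an adjusted p of 0.0844 with an estimated correlation, and of 0.0282 without array CS-PBS 4. Those called were Egr2 at 2.11 ± 0.28, Atf3 at 1.81 ± 0.26 and Nr4a1 at 1.78 ± 0.34. Genes of the type 2 response (4 of 16 higher, 5 adjusted over the list alone), with the chitinase-like gene Chil3 at 1.93 ± 0.23 and Retnla at 3.31 ± 0.66, had an adjusted p of 0.237 with an estimated correlation. Dendritic cell markers (3 of 13 higher, also adjusted over the list alone) had one of 0.0538. The same held for cholesterol synthesis, mucous cell, red blood cell and platelet, smooth muscle, alveolar type 1 and type I interferon lists, with adjusted p-values of 0.34, 0.345, 0.122, 0.34, 0.409 and 0.409 with an estimated correlation. Of these, cholesterol synthesis also failed camera without array CS-PBS 3, type I interferon without CS-PBS 4 (adjusted p = 0.199) or RA-PBS 5, alveolar type 1 without CS-PBS 4 (0.162) and smooth muscle without CS-PBS 4 (0.116).

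The response to aryl hydrocarbons, the classical target of smoke constituents, did not pass: 0 of 11 genes were called (1 adjusted over the list alone; 3900 probe sets had an unadjusted p under 0.05). The list had a camera adjusted p of 0.604. The values were 0.55 ± 0.84 for Cyp1a1 and 0.79 ± 0.23 for Cyp1b1 (adjusted p = 0.052), both cytochrome genes of this pathway, 0.00 ± 0.23 for its repressor gene Ahrr and 0.20 ± 0.33 for Nqo1. The SEs rest on the spread of all 4 groups. Array RA-hBD2 2, outside this comparison, had Cyp1a1 at 11.72 (5.11 to 5.69 on the other RA-hBD2 arrays) and Nqo1 at 8.64 (6.34 to 6.55). That array widens the SEs of Cyp1a1 and Nqo1, so a response of these genes could be missed. Of 24 NRF2 antioxidant genes 3 rose (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.137): the cystine transporter gene Slc7a11 at 2.08 ± 0.38, Hmox1 at 0.95 ± 0.24 and the glutathione reductase gene Gsr at 0.55 ± 0.15. Hmox1 lost its call without array CS-PBS 4 (0.66, adjusted p = 0.0977), and Gsr without any one of CS-PBS 1, 2, 3 or 4 or RA-PBS 1, 4 or 5 (adjusted p between 0.0596 and 0.102). Of 15 glucocorticoid response genes 1 rose and 5 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.134), with Cdkn1a at -1.45 ± 0.26, Klf9 at -0.93 ± 0.22 and Map3k6 at -1.54 ± 0.40 beside Zbtb16. Without array CS-PBS 4 the NRF2, glucocorticoid and extracellular matrix lists passed camera (adjusted p of 0.0325, 0.0173 and 0.0408), with adjusted p-values of 0.454, 0.477 and 0.378 with an estimated correlation. Map3k6 lost its call without any one of CS-PBS 1 or 2 or RA-PBS 3, 4 or 5 (adjusted p between 0.0564 and 0.098). Egfr, the receptor of epidermal growth factor, fell by 1.74 ± 0.28 (adjusted p = 0.000339). No call was made for the chemokine receptor genes Ccr6 (0.16 ± 0.31), through which beta-defensins are known to act, and Ccr2 (0.51 ± 0.30) or for the endotoxin receptor gene Tlr4 (0.42 ± 0.18). Nor was one made for the mouse beta-defensin genes Defb4 (0.05 ± 0.24) and Defb14 (-0.38 ± 0.25) or the mucin genes Muc5ac (0.96 ± 0.90) and Muc5b (0.80 ± 0.62). The same was true of the chemokine genes Ccl20 (0.41 ± 0.29) and Cxcl13 (1.12 ± 0.65), Il6 (0.31 ± 0.20) and the neutrophil alarmin gene S100a8 (0.94 ± 0.31). Camera adjusted p-values of the lists for heat shock (0.678), extracellular matrix (0.137), B cells (0.787), T and NK cells (0.648), eosinophils and mast cells (0.134), alveolar type 2 cells (0.363), club cells (0.239), ciliated cells (0.322), fibroblasts (0.215), cardiac muscle (0.63), skeletal muscle (0.947), fat (0.48), thymus (0.421) and nerve and mesothelium (0.193) did not pass. Of the sex-linked genes Eif2s3y, Uty and Kdm5d 0 were called here or in the other comparisons.

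Over all 22206 probe sets, 766 were higher and 431 lower in CS-PBS than in RA-PBS at an adjusted p under 0.05. Without array CS-PBS 4 the numbers were 509 and 225. Camera passed 19 lists up and 4 down of 40, and 13 of them passed with an estimated correlation. On list scores per array, an exact two-sided permutation test passed 16 of 40 lists, 14 higher and 2 lower. Each had an exact p of 0.0159, the smallest these group sizes allow, and an adjusted p of 0.0397, and the lysosome list had a difference of 1.83. The score difference of the interferon gamma list was 0.96 (adjusted p = 0.121).

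**Figure D1:**
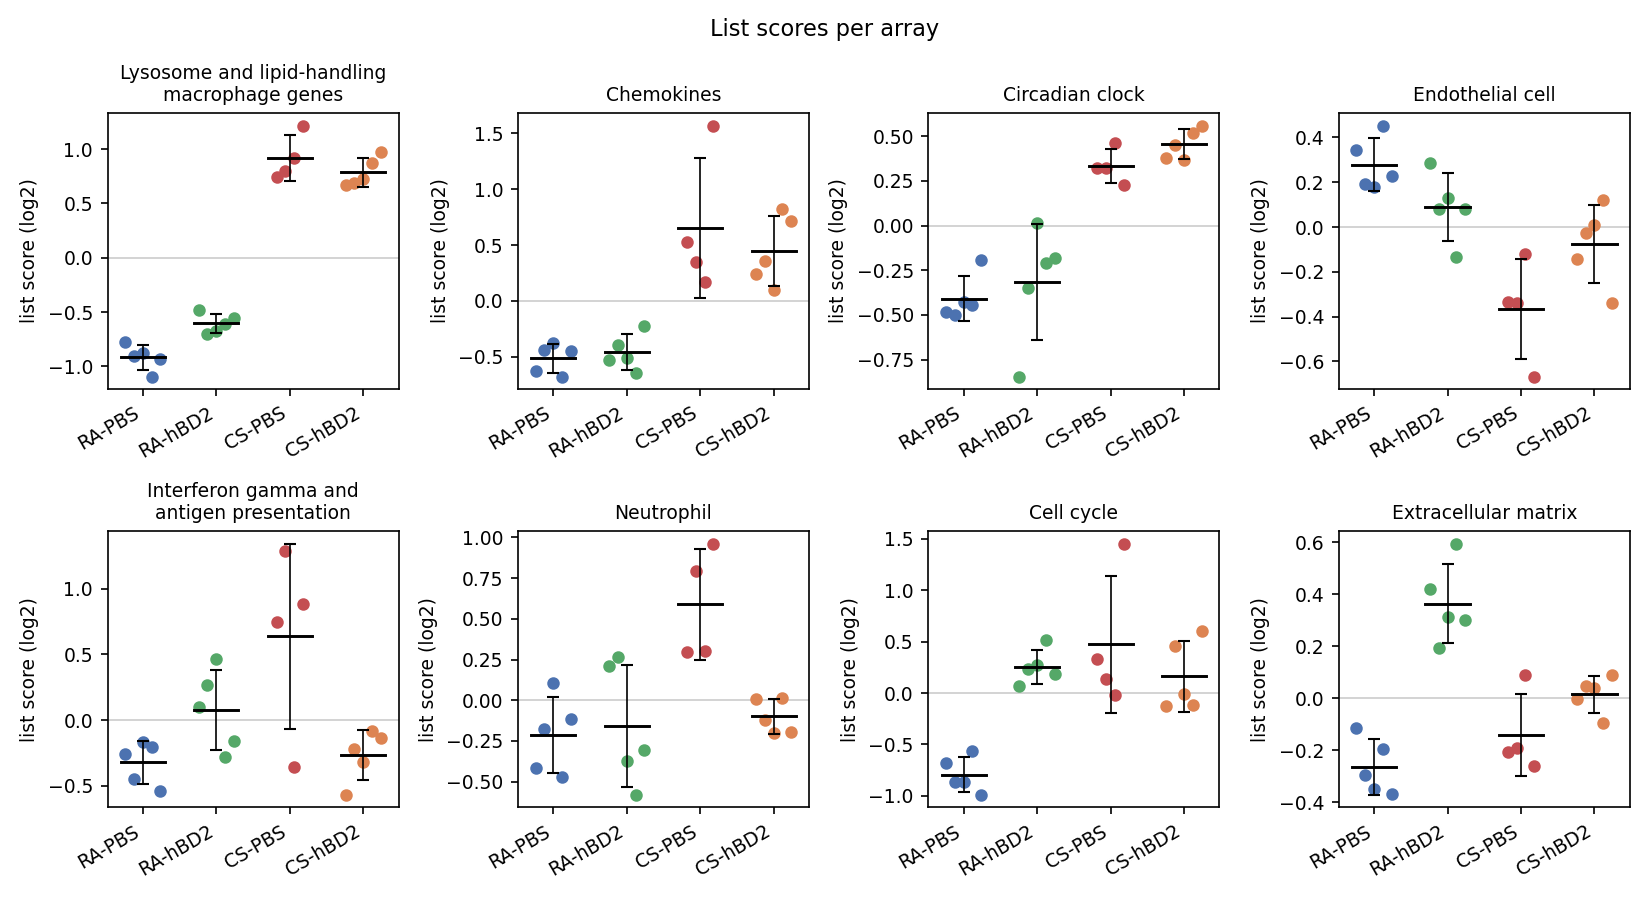
Each point is 1 array; the y axis is the mean over a list's genes of the log2 value minus that gene's mean over all 19 arrays, the black line the group mean and the bar the SD (n = 4 for CS-PBS, 5 in the other groups). Array CS-PBS 3 lies at -0.36 for interferon gamma and antigen presentation, and the lowest RA-hBD2 cell cycle score, 0.07, lies above the highest RA-PBS score, -0.56.

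The next comparison asked what hBD2 did in smoke-exposed lungs (CS-hBD2, n = 5, against CS-PBS, n = 4). No single gene passed. The smallest p-values belonged to Zbtb16, at 1.83 ± 0.30 (adjusted p = 0.0827), the immune-cell membrane gene Ms4a6c at -1.25 ± 0.21 (0.0827) and the semaphorin receptor gene Plxna2 at 0.92 ± 0.16 (0.0983). Next were Dock2, a guanine nucleotide exchange factor of white blood cells, at -0.86 ± 0.16 and the ATP receptor gene P2rx1 at 1.11 ± 0.21 (0.121 each), the latter from 4.44 in CS-PBS, within the background. Interferon gamma and antigen presentation genes were the list with the smallest camera p. Of its 17 genes 0 were called over all probe sets and 16 were lower adjusted over the list alone (camera adjusted p = 5.77e-22, and adjusted p = 0.104 with an estimated correlation). The interferon-induced GTPase genes Igtp, Gbp2 and Irgm1 were at -1.52 ± 0.39, -1.12 ± 0.28 and -1.01 ± 0.26. Neutrophil markers (0 of 16 called, 9 lower adjusted over the list alone) had an adjusted p of 0.0905 with an estimated correlation. They included the growth factor receptor gene Csf3r at -1.28 ± 0.31, the protease inhibitor gene Stfa2l1 at -1.58 ± 0.41, Asprv1 (within the background in both groups, at 4.74 and 3.93) at -0.80 ± 0.24 and S100a8 at -1.04 ± 0.31. T and NK cell markers (0 of 20 called, 4 lower adjusted over the list alone) had an adjusted p of 0.125 with an estimated correlation, with the granzyme gene Gzmb at -0.89 ± 0.27 and Ccl5 at -1.17 ± 0.39. Monocyte markers (0 of 16 called, 3 lower adjusted over the list alone) had one of 0.172, with the antibody receptor gene Fcgr1 at -1.36 ± 0.33 and the integrin gene Itgam at -0.94 ± 0.28. The smoke-responsive genes Mmp12 (0.67 ± 0.44), Saa3 (-0.11 ± 0.71), Cxcl5 (-0.71 ± 0.41), Cxcl1 (-0.37 ± 0.35), Tnf (-0.20 ± 0.47), Il1b (-1.10 ± 0.28) and Egfr (0.90 ± 0.28) did not pass. Nor did Ccr2 (-0.80 ± 0.30), Ccr6 (-0.65 ± 0.31) or Tlr4 (-0.21 ± 0.18).

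This comparison turned on 1 array. With limma 0 probe sets passed at an adjusted p under 0.05 and 1589 had an unadjusted p under 0.05, against 1110.3 that chance gives. With trend and robust estimates limma called 19. Without array CS-PBS 3, whose interferon gamma score lay among those of the CS-hBD2 arrays (-0.57 to -0.08), 26 probe sets were higher and 93 lower. That array was left out for its outcome, so the genes and lists called without it do not test the hBD2 effect. When that choice was repeated over 100 sample splits, another split called 131. Without CS-PBS 3, 11 of the 17 interferon gamma genes were lower. Among them were Igtp at -2.10 ± 0.29, Gbp2 at -1.55 ± 0.20 and Ciita at -1.29 ± 0.18 (adjusted p of 0.0016 each). Ccr2 was lower at -1.26 ± 0.22 (0.0112), Csf3r at -1.59 ± 0.30 (0.0154) and Il1b at -1.35 ± 0.28 (0.0325), while Zbtb16 was higher at 1.69 ± 0.32 (0.0171). Leaving it out let 4 lists pass with an estimated correlation, those of interferon gamma (adjusted p = 0.00782), neutrophils, monocytes and T and NK cells (0.0438 each). Genes were called in smaller numbers without CS-PBS 4 (2 probe sets, Nr4a1 at -1.94 with an adjusted p of 0.0254 and Zbtb16 at 1.99 with 0.0444), CS-hBD2 5 (2), RA-hBD2 3 (2) and RA-hBD2 4 (1). With all arrays camera passed 7 lists up and 11 down, 0 of which passed with an estimated correlation. The rotation test fry passed 2, interferon gamma and neutrophil, each with an adjusted p of 0.0438. The exact permutation test on list scores passed 0 of 40 (smallest exact p 0.0159, adjusted p = 0.212). No smaller exact p is possible with these group sizes, so after adjustment a list can pass only if enough lists reach it. Lists that camera passed here and that are not named above had an adjusted p of 0.172 or more with an estimated correlation.

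In room air, cell division and matrix genes were higher in hBD2-treated lungs (RA-hBD2, n = 5, against RA-PBS, n = 5). The mitotic genes Pbk, Racgap1, Plk1 and Cdc20 rose by 2.44 ± 0.36 (5.43-fold), 1.71 ± 0.27, 1.70 ± 0.26 and 1.66 ± 0.26 (adjusted p of 0.00597 each), and the histone gene H2bc13 by 1.81 ± 0.29 (adjusted p = 0.00597). Sprr1a, a cornified-envelope gene of squamous epithelium, rose by 1.84 ± 0.32 (3.58-fold, adjusted p = 0.0148). The size of the rise is uncertain for Sprr1a, Cdc20 and Col5a1, whose RA-PBS means of 3.95, 4.69 and 4.49 were within the background. Zbtb16 fell by 2.09 ± 0.28 (4.25-fold lower, adjusted p = 0.00502). These 7 genes kept their call whichever array was left out. Of 22 cell cycle genes 5 rose and 18 were higher adjusted over the list alone (camera adjusted p = 2.08e-25, and adjusted p = 0.0357 with an estimated correlation). Without array CS-PBS 4, which enters through the shared spread, 10 of the 22 were called. Of 19 extracellular matrix genes 5 rose and 14 were higher adjusted over the list alone (camera adjusted p = 2.11e-16, and adjusted p = 0.00373 with an estimated correlation). Matrix genes that passed included the glycoprotein gene Tnc at 1.83 ± 0.33, the fibronectin gene Fn1 at 0.82 ± 0.17 and the collagen genes Col1a2 at 0.90 ± 0.19 and Col5a1 at 0.80 ± 0.16. Proteases and antiproteases rose as a list with 0 of 22 genes called (6 higher adjusted over the list alone; adjusted p = 0.0314 with an estimated correlation). Mmp2 was at 1.06 ± 0.24 and Mmp12 at 1.76 ± 0.41, with adjusted p-values of 0.0528 and 0.0648.

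Ccnb2, H1f1 and Mki67, genes of dividing cells, also passed in room air, at 1.91 ± 0.36, 1.79 ± 0.34 and 1.74 ± 0.32. So did the surfactant protein gene Sftpd at 0.73 ± 0.14, the metallothionein gene Mt2 at 0.90 ± 0.19 and the growth factor binding protein gene Igfbp2 at 0.91 ± 0.19. Lower were the glucocorticoid-induced genes Tat (-1.46 ± 0.29) and Klf15 (-1.24 ± 0.24), the binding protein genes Igfbp6 and Igfbp3 (both -1.14 ± 0.23) and Galnt15 (-1.32 ± 0.27). Med12l (-0.99 ± 0.19), the Notch target Hey1 (-0.97 ± 0.20) and the ciliary genes Dnaaf4 (-0.84 ± 0.17) and Hydin (-0.81 ± 0.17) were lower too. Tat and Dnaaf4 were at 3.65 and 4.49 in RA-hBD2, within the background, so the sizes of these falls are uncertain. Of the 26 named genes that passed in this comparison, these and the matrix genes, 19 in all, lost their call without some array. Tnc, Mki67 and Sftpd did so for 4 arrays each, Ccnb2 and Klf15 for 5, and H1f1, Igfbp6, Igfbp3, Med12l, Dnaaf4 and Col5a1 for 7. It was so for Tat, Galnt15, Igfbp2 and Col1a2 for 8, for Hey1, Hydin and Fn1 for 9 and for Mt2 for 11, with adjusted p-values between 0.0504 (Mt2) and 0.105 (Fn1). The arrays behind these lost calls were all 5 RA-PBS and all 5 RA-hBD2 arrays, and for Mt2 also CS-PBS 1 and CS-hBD2 2.

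Further lists passed camera in room air and not with an estimated correlation. Lysosome genes (0 of 20 called, 5 higher adjusted over the list alone) had an adjusted p of 0.0993 with it, and red blood cell and platelet genes (0 of 8 called, 5 lower adjusted over the list alone) one of 0.0599. Type I interferon, mucous cell and alveolar type 2 lists had one of 0.18 each. Interferon gamma genes (0 of 17 called, 1 higher adjusted over the list alone), ciliated cell markers and glucocorticoid response genes (1 of 15 higher, Mt2, and 1 lower, Zbtb16; 2 and 4 adjusted over the list alone) had adjusted p-values of 0.431, 0.281 and 0.437 with an estimated correlation. The glucocorticoid list ended its camera call without array RA-hBD2 1. The lists of aryl hydrocarbon (camera adjusted p = 0.81), NRF2 (0.507), chemokine (0.767) and clock genes (0.479) did not pass.

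In all, 62 probe sets were higher and 15 lower with hBD2 in room air, and 2225 had an unadjusted p under 0.05. The count was 21 without RA-PBS 3, 31 without RA-PBS 4, and 35 without RA-PBS 5. It was 34 without RA-hBD2 1, 36 without RA-hBD2 2, 35 without RA-hBD2 3, 36 without RA-hBD2 4 and 46 without RA-hBD2 5. It was 141 without CS-PBS 4, which enters only through the shared spread. Camera passed 17 lists up and 5 down, of which 3 held with an estimated correlation, those of cell cycle, matrix and proteases. On list scores per array the differences were 1.05 ± 0.11 for cell cycle and 0.63 ± 0.08 for matrix, with no overlap of the groups. The exact permutation test passed 0 of 40 lists (smallest exact p 0.00794, adjusted p = 0.0529). That exact p is the smallest these group sizes allow, so after adjustment a list can pass only if enough lists reach it.

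Smoke was then compared in hBD2-treated lungs (CS-hBD2, n = 5, against RA-hBD2, n = 5). Macrophage and inflammatory genes again rose. Cxcr1 rose by 5.14 ± 0.37 (35.2-fold, adjusted p = 1.01e-08), Saa3 by 5.07 ± 0.67 (33.7-fold, adjusted p = 7.73e-05), and Ear6 by 4.95 ± 0.36 (30.8-fold, adjusted p = 1.36e-08). Gpnmb rose by 4.20 ± 0.26 (18.3-fold, adjusted p = 2.9e-09) and Mmp12 by 3.19 ± 0.41 (9.14-fold, adjusted p = 6.28e-05). Ly6i, Marco, Wfdc17, Ctsk, the zinc transporter gene Slc39a2 and the defensin-like gene Spag11b rose by 4.62 ± 0.33, 3.71 ± 0.25, 3.57 ± 0.25, 3.32 ± 0.20, 3.21 ± 0.30 and 3.55 ± 0.45. Fam124b (-2.51 ± 0.26), the matrix protein gene Spon2 (-2.14 ± 0.29), Arntl (-2.10 ± 0.22) and the elastin gene Eln (-1.90 ± 0.28) fell. So did Ccnjl (-1.62 ± 0.26), Scgb1c1 (-1.34 ± 0.24) and Adamts17 (-1.08 ± 0.22). Npas2 (-1.71 ± 0.36) lost its call without array CS-hBD2 1 (-1.53, adjusted p = 0.0505). Pgc (-1.16 ± 0.25) did so without CS-hBD2 2 or 4 or RA-hBD2 1 or 4 (adjusted p between 0.0582 and 0.0594), and Cttnbp2 (-1.15 ± 0.26) without CS-hBD2 2 (0.067) or 5 (0.0864) or RA-hBD2 1 (0.0601) or 4 (0.059). Cxcl5 (2.61 ± 0.39), Cxcl1 (1.83 ± 0.33), Lcn2 (1.39 ± 0.18) and Cyp1b1 (1.08 ± 0.22, adjusted p = 0.0108) rose, and Il1b (-0.08 ± 0.27) and Egfr (0.00 ± 0.26) did not pass. Background was reached by Cxcl5 (3.82), Cxcl1 (4.05) and Spag11b (4.72) in RA-hBD2 and by Pgc (4.62) in CS-hBD2, so the sizes of their differences are uncertain.

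By list, 13 of 20 lysosome genes rose in hBD2-treated lungs (16 adjusted over the list alone; adjusted p = 1.07e-05 with an estimated correlation), with Atp6v0d2 at 2.53 ± 0.18 and the galectin gene Lgals3 at 1.85 ± 0.20. So did 9 of 16 alveolar macrophage markers (10 higher and 3 lower adjusted over the list alone; adjusted p = 0.000377), with Plet1 at 1.56 ± 0.13. Chemokines rose in 9 of 27 genes (12 higher and 1 lower adjusted over the list alone; adjusted p = 0.0163 with an estimated correlation), with Ccl6 at 2.41 ± 0.18, Ccl3 at 2.40 ± 0.39 and Ccl22 at 2.22 ± 0.29. NF-kB genes rose in 5 of 24 (12 adjusted over the list alone; adjusted p = 0.000564), with Csf2 at 1.61 ± 0.21 and Il1a at 1.48 ± 0.21. Of 17 clock genes 9 rose and 3 fell (11 and 4 adjusted over the list alone; adjusted p = 0.0018 with an estimated correlation), with Per2 at 2.40 ± 0.30, Bhlhe41 at 2.01 ± 0.20 and Per3 at 1.69 ± 0.25. Proteases (4 of 22 higher; 6 higher and 1 lower adjusted over the list alone) and iron handling (2 of 14 higher; 6 and 2 adjusted over the list alone) passed too, each with an adjusted p of 0.0209 with an estimated correlation. Cell cycle (0 of 22 called, camera adjusted p = 0.623), neutrophil (0 of 16, 0.518) and monocyte lists (1 of 16 higher, 0.146) did not pass. Without array CS-PBS 4 the monocyte list had 4 genes called and a camera adjusted p of 0.0192, and its adjusted p was 0.261 with an estimated correlation. Interferon gamma (0 of 17 called, on the lower side), endothelial (0 of 14, lower), complement (0 of 12, higher), matrix (1 of 19 lower, Eln) and NRF2 lists (0 of 24, higher) passed camera and had adjusted p-values of 0.527, 0.411, 0.27, 0.0757 and 0.109 with an estimated correlation. The matrix list had one of 0.0416 without array CS-PBS 3, and 4 complement genes were called without CS-PBS 4. Of these, interferon gamma also failed camera without CS-hBD2 1 or RA-hBD2 3, and the endothelial list without CS-hBD2 5 or RA-hBD2 1. In all, 206 probe sets were higher and 45 lower, and camera passed 14 lists up and 9 down, of which 7 held with an estimated correlation. The exact permutation test on list scores passed 8 of 40 lists, 7 higher and 1 lower (adjusted p of 0.0397 for each).

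The smoke effects in vehicle-treated and hBD2-treated lungs share no arrays and could be set against each other directly. Across probe sets, which are not independent replicates, they correlated with r = 0.459 (jackknife SE 0.0584), against 0.000528 in simulations with no effect. The slope of the second on the first, corrected for noise, was 0.488 (SE 0.113). Of the called probe sets 180 were higher in both, where independent lists would share 7.11, and 23 were lower in both, where 0.873 would be shared, and 0 were called in opposite directions. The 766 probe sets that rose in vehicle-treated lungs had a median of 1.08 there and of 0.41 in hBD2-treated lungs, where 650 of them lay on the same side of 0. The 431 that fell had medians of -0.78 and -0.20, with 353 on the same side. Probe sets chosen by size in 1 comparison are smaller in another by chance alone. In the other direction, the 206 that rose in hBD2-treated lungs had a median of 1.18 there and of 1.46 in vehicle-treated lungs, and the 45 that fell had medians of -0.86 and -0.70.

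**Figure D2:**
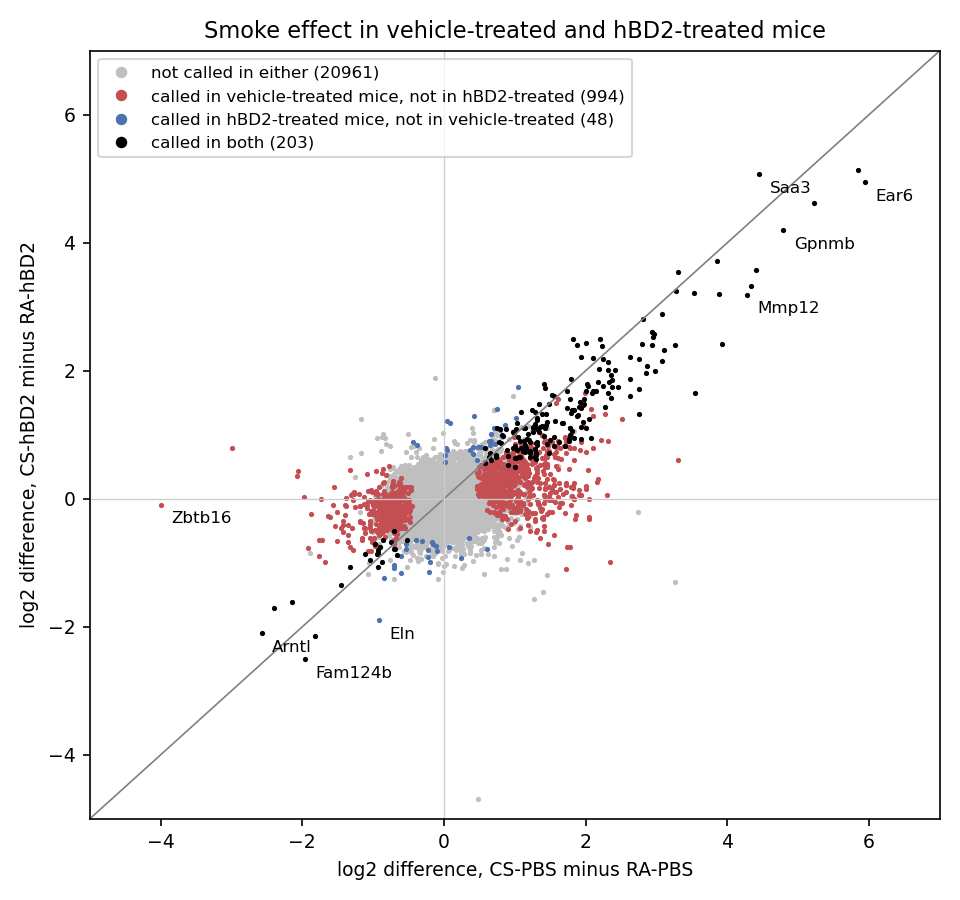
Each point is 1 of 22206 probe sets; the x axis is the log2 difference of CS-PBS minus RA-PBS and the y axis that of CS-hBD2 minus RA-hBD2, colours mark probe sets called in 1 comparison, both or neither, and the grey line marks equal differences. The 203 probe sets called in both share their direction, 180 higher and 23 lower, and Zbtb16 lies at -4.00 on the x axis and near 0 on the y axis.

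Whether smoke and hBD2 acted other than additively was tested as the difference of the hBD2 effect in smoke and in room air (all 4 groups). Zbtb16 stood out: it was at 16.03 in RA-PBS, 13.94 in RA-hBD2, 12.02 in CS-PBS and 13.85 in CS-hBD2, an interaction of 3.91 ± 0.41 (adjusted p = 7.51e-05) that kept its call whichever array was left out. Plxna2 (1.27 ± 0.22) and the ephrin gene Efnb1 (1.31 ± 0.24) were the other genes with a positive interaction. It was negative for the mitotic genes Racgap1 (-2.50 ± 0.40), Ckap2l (-1.97 ± 0.34) and Pbk (-2.81 ± 0.52) and the histone genes H2bc9 (-1.76 ± 0.32) and H2bc13 (-2.25 ± 0.42). It was also negative for Ciita (-1.79 ± 0.30) and the immediate early gene Nr4a1 (-2.53 ± 0.46). Ckap2l was at 4.35 in RA-PBS, within the background, so the size of its interaction is uncertain. These 9 genes had adjusted p-values between 0.029 and 0.0497 and each lost its call without any one of 10 to 16 arrays, with adjusted p-values between 0.0504 and 0.124. Pbk, for example, was at 4.93 in RA-PBS, 7.37 in RA-hBD2, 6.66 in CS-PBS and 6.29 in CS-hBD2, and Ciita at 9.13, 9.92, 10.44 and 9.44. Egfr (1.74 ± 0.38, adjusted p = 0.105), Il1b (-1.30 ± 0.39, 0.249) and Mmp12 (-1.09 ± 0.60, 0.684) did not pass.

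As lists, interferon gamma (1 of 17 called, 16 lower adjusted over the list alone) and cell cycle genes (0 of 22 called, 16 lower adjusted over the list alone) had a negative interaction. So had type I interferon (0 of 21 called, 6 lower adjusted over the list alone), immediate early (1 of 17 called, Nr4a1; 4 lower), neutrophil (0 of 16; 2 lower) and monocyte genes (0 of 16; 0 lower). Lysosome (0 of 20 called, 3 lower adjusted over the list alone), matrix (0 of 19; 3 lower) and protease genes (0 of 22; 1 lower) did as well, and red blood cell and platelet genes (0 of 8 called, 5 higher adjusted over the list alone) had a positive one. Each of these 10 lists had an adjusted p of 0.0494 with an estimated correlation. Complement, alveolar macrophage and endothelial lists passed camera and had adjusted p-values of 0.115, 0.0689 and 0.104 with an estimated correlation. Array CS-PBS 3 was left out for its outcome, so results without it do not test the interaction. Without that array the interaction was called for 10 of 17 interferon gamma genes and 4 of 22 cell cycle genes. There, 5 lists passed with an estimated correlation (interferon gamma, cell cycle, monocyte, type I interferon and red blood cell and platelet), and without CS-PBS 4, 4 lists (cell cycle, matrix, immediate early and red blood cell and platelet). The exact permutation test on list scores, with treatment labels permuted within each exposure, passed 9 of 40 lists, with differences of -1.30 for interferon gamma (adjusted p = 0.0307), -1.36 for cell cycle and 1.42 for red blood cell and platelet genes (adjusted p = 0.0101).

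The interaction was called for 3 probe sets up and 8 down, 1 of them unnamed here, and 1829 had an unadjusted p under 0.05. All 3 that were higher were among the probe sets lower with smoke in vehicle-treated lungs, and all 8 that were lower were among those higher there. Both comparisons hold the CS-PBS and RA-PBS arrays with opposite sign, so shared arrays alone favour such opposite calls, and no more is read from them. The count was 67 without CS-PBS 3, 1 without CS-PBS 1, 4 without CS-PBS 2 and 6 without CS-PBS 4. It was 1 without CS-hBD2 1, 2 or 3, 2 without CS-hBD2 4, 2 without RA-PBS 1, 1 without RA-PBS 3, 4 or 5, 1 without RA-hBD2 1 or 2, and 6 without RA-hBD2 5.

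**Figure D3:**
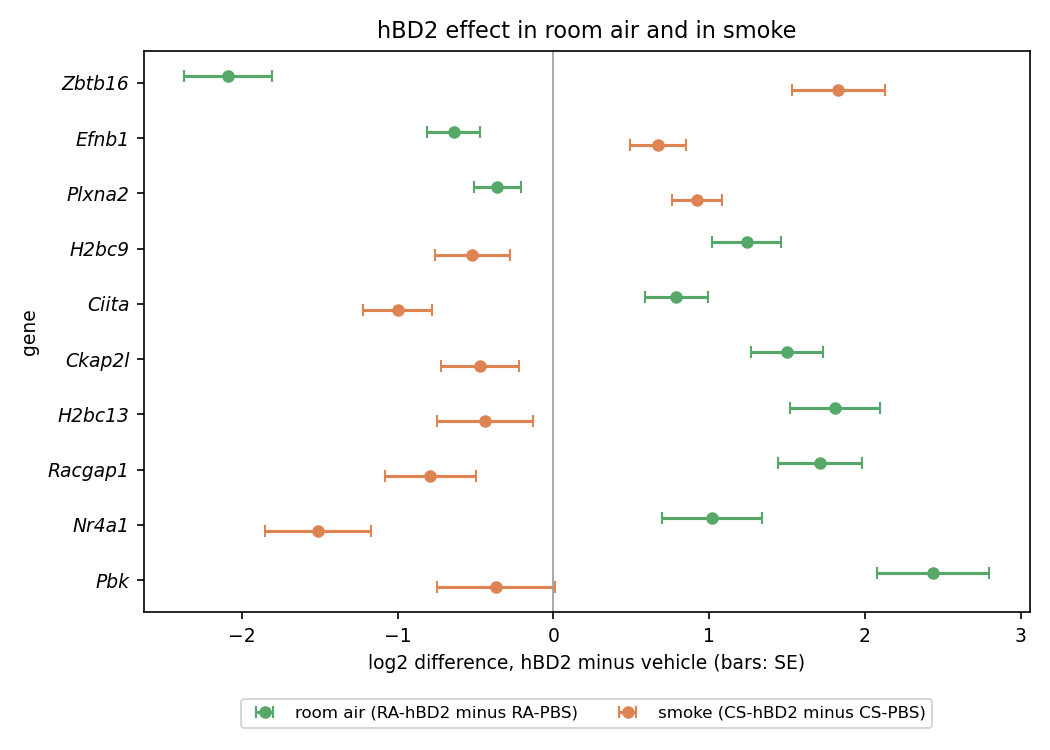
The x axis is the log2 difference between hBD2-treated and vehicle-treated lungs with its SE, in room air (RA-hBD2 minus RA-PBS, green) and in smoke (CS-hBD2 minus CS-PBS, orange), for the 10 named genes with a called interaction. For Zbtb16 the values are -2.09 ± 0.28 in room air and 1.83 ± 0.30 in smoke.

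Whether hBD2 opposed the smoke effect across the genome was asked from the correlation of CS-hBD2 minus CS-PBS with CS-PBS minus RA-PBS. It was -0.497 (jackknife SE 0.114), but both differences hold the CS-PBS arrays, and simulations with no effect gave -0.555. The covariance was -0.0527 against -0.0296 in the simulations, a difference of -0.0231 (jackknife SE 0.0243). With the CS-PBS arrays split between both differences, the mean over 6 splits was r = -0.133 (from -0.278 to -0.0256) and the mean covariance -0.0182. The hBD2 effects in room air and in smoke, which share no arrays, had r = -0.00757 (jackknife SE 0.0863).

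The hBD2 effect averaged over both exposures passed for 4 genes. Igfbp2 rose by 0.95 ± 0.14 (1.93-fold, adjusted p = 0.0101) and the gap junction gene Gja1 by 0.66 ± 0.10 (1.59-fold, adjusted p = 0.0101). The sialyltransferase gene St6galnac2 rose by 0.71 ± 0.11 and lost its call without array RA-PBS 2 (0.69, adjusted p = 0.0561). Brinp1, at 0.79 ± 0.13 (adjusted p = 0.0411), lost its own without any one of 13 arrays (adjusted p between 0.0518 and 0.135). Extracellular matrix genes rose as a list with 0 of 19 called over all probe sets (14 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.46e-13, and adjusted p = 0.00859 with an estimated correlation). Tnc was at 1.28 ± 0.24 and Fn1 at 0.61 ± 0.12, with adjusted p-values of 0.0533 and 0.0869. Cell cycle (0 of 22 called, 5 higher adjusted over the list alone) and T and NK cell lists (0 of 20) passed camera, up and down, and had adjusted p-values of 0.342 and 0.202 with an estimated correlation. Without array CS-PBS 4 the cell cycle list passed here, with 2 genes called and an adjusted p of 0.018 with an estimated correlation. The average was called for 4 probe sets up and 0 down (limma; 2013 had an unadjusted p under 0.05, and limma with trend and robust estimates called 46). The count was 52 without CS-PBS 3, 11 without CS-PBS 4, 2 without RA-PBS 2, 8 without RA-PBS 1 and 9 without RA-hBD2 2.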

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

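The splits of the samples with all arrays, the spread of array CS-PBS 4 over receptor probe sets and the quantile normalization of the room air comparison were tests set before their results were seen. The tests on clock genes, on liver and lymphoid RNA, on the gap between room air arrays, on the split RA-PBS arrays and on splits with the array of most calls left out were chosen only after the results were seen. A sample was singled out when its gap to the nearest of its group was larger than Dixon's ratio allows, which chance does in about 1 of 20 groups. That held for 8 of 164 group scores of lists (8.2 by chance), 33 of 564 groups of gene values (28.2 by chance) and 4 of 20 groups of array measures (1 by chance).

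Array CS-PBS 4 stood apart from the other arrays. Its mean correlation with the rest was 0.9835 (0.989 to 0.9897 on the other CS-PBS arrays), its first principal component -53.1 (-23.3 to -19.2), its NF-kB score 0.94 (0.26 to 0.31) and its club cell score -0.30 (-0.05 to -0.04). On this array Rrm2 was at 9.60 (7.48 to 7.81 on the others), Ccl3 at 12.92 (10.42 to 10.58), C1qa at 12.51 (10.31 to 10.63), Cdkn1a at 14.73 (13.76 to 13.87) and Slc7a11 at 10.36 (7.66 to 8.04). On it Hmox1 was at 12.76 (11.56 to 11.64), Ccnb2 at 10.38 (8.27 to 8.63), H1f1 at 9.26 (7.42 to 7.73), Eln at 12.89 (11.66 to 11.69) and St6galnac2 at 12.25 (12.56 to 12.61). A large share of liver RNA is argued against by 15 liver transcripts, whose median difference from the other 3 CS-PBS arrays was 0.25. A small share is not excluded. Several of these transcripts, such as Ttr (4.08 against 3.86) and Fga (4.12 against 4.12), were within the background on both sides. Alb, Serpinc1 and Apoa2 lay 2.99, 2.36 and 1.05 higher, while Mup3 was at -0.68. Lymph node RNA is argued against by a B cell score of 0 against a highest score of 0.30 elsewhere. For noise or poor RNA, the SD of the array's deviations over receptor probe sets was 0.379, rank 5 of 19, against 0.380 to 0.384 on the 4 arrays above it. By the rule set beforehand, a value at or below the highest of the other 18 arrays argues against noise. That rule held no margin for the sampling error of 0.00705, within which these arrays cannot be told apart, so noise is left open. Over all probe sets the SD was 0.433 against 0.378. A stronger response of that lung to smoke may also account for it and was not tested.

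Clock genes differed between smoke-exposed and room air lungs under both treatments. The 4 clock genes that fell in vehicle-treated lungs had a median of -1.13 (median SE 0.22) on the arrays of hBD2-treated lungs, which had no part in choosing them, below the 5th percentile (-0.32) of the medians of 10000 random sets of as many of 84 resident cell markers, which argues against dilution by incoming macrophages. The 8 that rose had a median of 1.74 (median SE 0.28) there, above the 95th percentile (1.33) of such sets of 48 macrophage markers by less than 2 SE, so added macrophage RNA stays open. A phase score, genes that peak with Dbp minus genes that peak with Arntl, was higher by 3.08 (SE 0.35) in CS-PBS than in RA-PBS (exact two-sided permutation p = 0.0159) and by 2.51 in CS-hBD2 than in RA-hBD2 (exact p = 0.00794), with the lowest smoke-exposed array at 0.87 and the highest room air array at 0.12. Another hour of sacrifice in smoke-exposed mice and a clock shifted by smoke would both give this, and the labels give no hour, so they cannot be told apart.

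In room air, cell cycle and matrix genes were higher with hBD2. The deposited values were already normalized across arrays, so a further quantile normalization could change little. It left 86 probe sets called and the cell cycle list past its threshold, and a shift to a common median left 61 called. This argues only against the distribution differences left between the deposited arrays as the whole cause. Against 1 or 2 outlying samples, the lowest RA-hBD2 cell cycle score lay 0.63 above the highest RA-PBS score. The smoke effect in vehicle-treated lungs and the hBD2 effect in room air, which share the RA-PBS arrays, had a covariance of 0.0597 against 0.0237 with no effect (r = 0.523 against 0.472). With the RA-PBS arrays split the mean covariance was still 0.0362 (r between 0.229 and 0.300 over 20 splits). RA-PBS arrays handled apart from the other groups and a response common to smoke and hBD2 may both give this, and no label names a batch, so they cannot be told apart.

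Of 100 sample splits, 1 (the real one) called as many probe sets as seen for smoke in vehicle-treated lungs (1197, highest other 369). It was so too for hBD2 in room air (77, highest other 5) and smoke in hBD2-treated lungs (251, highest other 2). The interaction (11, highest other 2) and the averaged hBD2 effect (4, highest other 1) gave the same share. By the preset rule of under 5 of 100 splits, chance alone is argued against for these counts. A share of 1 of 100 is the smallest this test can give. Where groups differ, splits that mix them also widen the spread, which lowers their counts. For hBD2 in smoke 0 were called, so all 100 splits call as many by construction and test nothing (93 of the 99 others called 0, highest other 13). Array CS-PBS 3 was left out for its outcome, so that choice was repeated in each split: with the smoke-exposed array of most calls left out, 2 of 100 splits called as many as the real one (119, highest other 131). The other of these splits left out CS-hBD2 5 and set CS-PBS 1, 2 and 4 against CS-PBS 3 and the remaining CS-hBD2 arrays, and 2 more splits with the same 3 arrays against the rest called 99 (without CS-hBD2 2) and 79 (without CS-hBD2 3). The gap between those 3 arrays and the others was found from these same counts, so they do not test it and chance is not excluded for it. Nor is chance excluded for the labelled groups, since the counts do not say with which of them CS-PBS 3 belongs. For lists called by camera at its preset correlation, 1 of 100 splits gave as many for hBD2 in room air (22, highest other 19). The same held for smoke in hBD2-treated lungs (23, highest other 22) and the interaction (22, highest other 21). The other splits passed a median of 13 lists for smoke in vehicle-treated lungs, 10 for hBD2 in smoke and 6 for hBD2 in room air. Their median was 9 for smoke in hBD2-treated lungs, 9 for the interaction and 8 for the average. At the preset correlation camera thus passed many lists under other groupings as well. Chance is not excluded for smoke in vehicle-treated lungs (5 of 100; 23, highest other 25), hBD2 in smoke (12 of 100; 18, highest other 20) or the average (11 of 100; 16, highest other 22).

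Among other scores far from their group, array RA-hBD2 2 had an aryl hydrocarbon score of 1.03 (-0.36 to -0.21 on the others) and a thymus score of 0.64 (-0.12 to 0.10), and on it Cyp1a1 was at 11.72 (5.11 to 5.69), Cyp1b1 at 7.00 (6.06 to 6.28), Nqo1 at 8.64 (6.34 to 6.55) and Tnf at 7.19 (5.88 to 6.24). The type I interferon score of RA-hBD2 5 was -0.19 (0.21 to 0.36), the clock score of RA-PBS 5 -0.19 (-0.50 to -0.43), the heat shock score of RA-hBD2 1 -0.50 (-0.06 to 0.07) and the nerve and mesothelium score of RA-PBS 1 0.55 (0.11 to 0.21). The median of CS-PBS 3 was 6.78 (6.73 on the others) and the second principal component of CS-hBD2 1 was 12.4 (-20.6 to -11.1). In CS-PBS, Ccl6 was at 15.57 on array 1 (16.15 to 16.20) and Csf2 at 5.76 on array 3 (6.24 to 6.27). In CS-hBD2, Gp9 was at 7.90 on array 1 (6.50 to 6.87), and on array 2 Ctsk was at 12.45 (12.83 to 12.90) and Map3k6 at 7.26 (6.55 to 6.72). There C1qa was at 10.90 (10.04 to 10.26) and Egfr at 6.67 (7.30 to 7.37) on array 4, and Ccnjl at 6.12 (7.26 to 7.57), Ccl20 at 6.19 (5.48 to 5.65) and Muc5ac at 8.93 (3.83 to 5.05) on array 5. In RA-PBS, Cdkn1a was at 14.68 (15.58 to 15.92) and Tat at 3.94 (5.24 to 5.57) on array 2, H2-Eb1 at 15.04 on array 3 (14.60 to 14.72), Wfdc17 at 7.86 on array 4 (8.68 to 8.86) and Gp9 at 9.23 on array 5 (7.75 to 8.10). In RA-hBD2, Cxcl5 was at 4.63 (3.44 to 3.76) and Ahrr at 3.78 (4.81 to 5.15) on array 1, Ckap2l at 6.06 on array 4 (5.77 to 5.82) and Tat at 4.64 on array 5 (3.13 to 3.55).

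The hBD2 effect differed between smoke and room air, by the interaction term, for Zbtb16 (3.91), Efnb1 (1.31), Plxna2 (1.27), H2bc9 (-1.76), Ciita (-1.79), Ckap2l (-1.97), H2bc13 (-2.25), Racgap1 (-2.50), Nr4a1 (-2.53) and Pbk (-2.81). By the exact permutation test on list scores it differed for red blood cell and platelet (1.42), endothelial (0.48), lysosome (-0.44), type I interferon (-0.60), complement (-0.65), monocyte (-0.67), immediate early (-0.73), interferon gamma (-1.30) and cell cycle genes (-1.36). Of the 10 genes, only Zbtb16 kept its call whichever array was left out. The interaction holds the RA-PBS arrays, so RA-PBS arrays handled apart from the other groups may also give these differences. No label names a batch, so this cannot be told apart from an hBD2 effect that differs between exposures.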

How the results depend on the processing

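Among the settings here, the lists with an estimated correlation without array CS-PBS 3 or CS-PBS 4 were chosen after seeing the data, and the others before. Counts of probe sets are compared with those of the model of all arrays: 1197 for smoke in vehicle-treated lungs (64.0% higher), 0 for hBD2 in smoke, 77 for hBD2 in room air, 251 for smoke in hBD2-treated lungs, 11 for the interaction and 4 for the averaged hBD2 effect. Where a count moved by over 1.5 times, the cause was not tested unless the setting itself removes probe sets or arrays. Differences of probe sets near the receptor background are the ones that the signal limits most.

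For smoke in vehicle-treated lungs, a fit on only the groups compared called 731 and an adjusted p under 0.1 called 1802; with arrays shifted to a common median 54.3% of calls were higher. For hBD2 in smoke, trend and robust estimates called 19, the median filter 4, array weights 1 and an adjusted p under 0.1 called 3. For hBD2 in room air, trend and robust estimates called 145, the median filter 131, array weights 122 and an adjusted p under 0.1 called 207. For smoke in hBD2-treated lungs all settings stayed within 1.5 times. For the interaction, trend and robust estimates called 39, quantile normalization 6 (3 higher and 3 lower) and a common median 4 (2 and 2). For the average, trend and robust estimates called 46, the filters at the 25th percentile and the median 13 and 15, array weights 20, probe sets with 1 symbol 11 and an adjusted p under 0.1 called 18.

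Leaving out 1 array each gave 734 (without CS-PBS 4) to 1223 calls for smoke in vehicle-treated lungs, 0 to 119 (without CS-PBS 3) for hBD2 in smoke, 21 (without RA-PBS 3) to 141 (without CS-PBS 4) for hBD2 in room air, 1 to 67 (without CS-PBS 3) for the interaction and 2 (without RA-PBS 2) to 52 (without CS-PBS 3) for the average.

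With an estimated correlation, 13, 0, 3, 7, 10 and 1 lists passed for smoke in vehicle-treated lungs, hBD2 in smoke, hBD2 in room air, smoke in hBD2-treated lungs, the interaction and the average, against 23, 18, 22, 23, 22 and 16 with the preset one. Fry passed 2 for hBD2 in smoke, 6 for hBD2 in room air, 11 for smoke in hBD2-treated lungs, 12 for the interaction and 2 for the average. The correlation of both smoke effects was 0.571 with the median filter. Scores taken as medians over members left 0 lists past the threshold for smoke in hBD2-treated lungs, against 8.

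With the replicate number as a replicate block, the counts were 1137, 1, 64, 242, 11 and 1. Nothing in the labels pairs the arrays. Deviations of samples from their group means had a median r of 0.011 over 27 pairs of the same number and of -0.006 over 108 pairs of different numbers, with 3 pairs above 0.1 in each. The highest of all was CS-PBS 1 with CS-hBD2 1 (0.181), followed by CS-PBS 3 with CS-hBD2 3 (0.147). As a hint from the data, 7 of 19 arrays correlated best with their own number, so not every one did.

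Of the 203 named gene values, 148 passed. Quantile normalization ended 7 of those calls, trend and robust estimates ended 3 and added 11, the replicate block ended 13 and added 4, and 0 changed direction under any of these.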

Other observations

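The lists discussed here were fixed before the data were examined, and the choice to describe these values was made after they were seen.

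Mucous cell scores ran from -1.12 to 2.03 in CS-hBD2, where array CS-hBD2 5 held the highest score together with a type 2 score of 1.88, and from -2.70 to 0.11 in RA-PBS. In room air with hBD2 the mucous list had a median of 1.23 over 12 genes, with 0 of them called (3 higher adjusted over the list alone), and an adjusted p of 0.18 with an estimated correlation. Red blood cell and platelet scores lay between 0.28 and 0.80 in RA-PBS, from -0.94 to 0.46 in RA-hBD2, from -0.68 to -0.08 in CS-PBS and from 0.10 to 0.32 in CS-hBD2. Heat shock genes had 3 of 14 members higher in smoke with hBD2 (adjusted p = 0.109 with an estimated correlation), and cardiac muscle markers, of which 0 of 13 were called in room air, had an adjusted p of 0.327 with an estimated correlation there.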
